A study of Mus musculus with 6 samples.

How the data were processed

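RNA from the ileum of 3 wild type and 3 TLR4ΔIEC mice, all C57BL/6 and 24 weeks old, was studied. Per the labels' protocols, tissue was snap frozen, total RNA of good integrity was depleted of ribosomal RNA, spike-in RNA was added, the RNA was fragmented with RNase III, and Ion Torrent whole-transcriptome libraries were made with strand-specific reverse transcription and PCR amplification. Per the series' design text, each mouse had its own barcode, and the libraries of each genotype were pooled and sequenced apart from the other genotype. TopHat2 2.0.10, Bowtie2 2.1.0 and build mm10 are named in the submitters' processing notes, which give no roles. The tool that made the coverage values, the read length and whether counting used strand are not given in the sources used here.

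The deposited unit, per the file headers, is average coverage per RefSeq transcript entry, 1 column for each genotype. Per the labels, each column belongs to all 3 mice of its genotype, so it was treated as a pool, with no replicates. The deposited coverage was not scaled to library size: 99.99% of values in each column were a whole number divided by a whole number of bases (tolerance 1e-11), as summed bases of reads over a length give. Among weakly covered genes, that length often equalled the sum of only some exons: for single-transcript genes of 2 to 8 exons with coverage under 0.1, this held for 31.3% of wild type and 32.6% of TLR4ΔIEC values, against 2.53% and 2.40% when 7 bases were added to the length. At a coverage of 10 or more it held for 2.85% and 3.41%. The full length was matched by 4.52% and 4.70% of values under 0.1 and by 10.3% and 9.85% at 10 or more. Most values thus matched neither, and the rule behind them is not known. Among weakly covered genes the average appears, for a part of them, to run over exons with reads, which would raise their values. The same length lay behind both averages for 80.6% of the genes analysed and 39.5% of the weaker ones.

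Both columns listed 22001 entries, which gave 21950 gene symbols, since 51 entries repeated a symbol; such a gene was represented by its entry with the highest mean. Entries listed only in the wild type column (723, highest coverage 6.84) or only in the TLR4ΔIEC column (686, highest coverage 5.82) were left out and not taken as 0. The columns were put on 1 scale by the median of ratios (factor 1.05) and to a mean total of 1000000 units, and log2 ratios were taken of values plus a pseudocount of 1, which understates the ratios of weakly covered genes. Genes with a mean of at least 5 units were kept (8888 genes, corresponding to a coverage of 3.41 in wild type and 3.58 in TLR4ΔIEC). Since the read length is not given, coverage was not turned into read numbers, and no counting intervals or floors are given. The 50 highest entries held 47.6% of the wild type and 48.8% of the TLR4ΔIEC sum.

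The comparison, 42 gene lists, the filter, the pseudocount, the scaling and the rule for named genes were fixed before the data were examined. A test across mice had been planned. The pooled columns do not allow it, so the plan for data without replicates was followed, and a difference is one between 2 pooled columns with no replicate check and no p-value. Each list of at least 3 measured genes was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Named genes were Tlr4, the 12 highest and the 12 lowest log2 ratios among genes with a mean of at least 20 units, and of each list described up to 4 members with the largest absolute ratio above that level. Unnamed models and small noncoding RNAs were counted and not named, and a few list members that the rule takes are not reported here. Genes chosen after their values were seen are marked as such.

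Coordinates are from GENCODE vM21 (GRCm38, the assembly behind mm10), in which 94.1% of the symbols were found, 99.7% of them on the chromosome given in the deposited table; symbols missing there were matched by RefSeq accession to the NCBI annotation of the same assembly. The steps were tested on data simulated from the geometric mean of both columns, with the observed spread of ratios as noise and known differences put in. A scaling factor of 1.5 was found as 1.52. Log2 differences of -2, -1, 1 and 2 were found as -1.93, -0.95, 0.98 and 1.72. All 40 shifted lists of 15 genes, and 3.00% of 200 unshifted ones, lay outside the central 95% of random lists. The shift put in was 1 log2 unit for every member, more than the medians of most real lists found outside that range. Noise was drawn gene by gene, while genes of a real list are not independent, so 3.00% is not their rate of false calls. Alternatives were 4 other scalings, 2 other pseudocounts, 3 other filters, the mean over entries of a symbol, removal of the trend of the ratio with GC content and length, and genes with the same length behind both averages only. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.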

Results

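Ileum, the last part of the small intestine, was compared between genotypes in C57BL/6 mice at 24 weeks of age, with 3 mice in the wild type group and 3 in the TLR4ΔIEC group. TLR4ΔIEC mice carry a conditional deletion, in intestinal epithelial cells, of Toll-like receptor 4 (Tlr4), the receptor through which cells sense bacterial lipopolysaccharide. Whole-transcriptome libraries were made from total RNA depleted of ribosomal RNA, 1 library per mouse. The deposited values were 1 column of average coverage per genotype, each described as shared by its 3 mice, so every value below is that of a pooled column. No value per mouse was used, no spread between mice can be given, and no test was possible. The wild type column listed coverage for 22724 transcript entries with a median of 1.57 reads per base and a sum of 699800, and the TLR4ΔIEC column listed 22687 entries with a median of 1.70 and a sum of 698473. Over the 12320 genes with the same recoverable length behind both averages, coverage times that length summed to 711 and 709 megabases. The recovered length can be a divisor of the true one, so these sums may be too low. The depth over the other genes is not known. The 3 libraries of each genotype were sequenced as a pool of their own, so the genotype and the sequencing pool cannot be told apart in any comparison here.

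The first question was the level of the targeted gene. Tlr4 (chromosome 4, 66827584 to 66930284, plus strand, mm10) had a coverage of 1.98 in the wild type column and 1.60 in the TLR4ΔIEC column, or 2.90 and 2.24 units after both columns were scaled to a mean total of 1000000 units, a log2 ratio of -0.27. This rested on 7621 and 6158 bases of reads over a recovered length of 3846 bases. Among 2338 genes of similar level, the ratio lay at the 21.6th percentile, so it did not stand apart from other weakly covered genes. The value covers the whole transcript in whole ileum, in which cells other than the epithelium keep the gene, and the deleted part was not isolated, so it checks the genotype labels only weakly. Of 16 measured genes of TLR4 signalling, 0 differed by 2-fold or more, 6 lay above 0 and 10 below, and their median log2 ratio of -0.14 lay at the 7.18th percentile of random lists matched on expression. Relb, a subunit of NF-κB, had the lowest ratio among the well covered members (-0.85), followed by the adaptor Ticam1 (-0.33) and the inhibitor Nfkbia (-0.23), while the adaptor Myd88 was at -0.10. The lipopolysaccharide co-receptor Cd14, weakly covered and chosen after its value was seen, was at 0.78 (10.8 units in wild type and 19.3 in TLR4ΔIEC).

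The second question was which genes differed between the ileum of TLR4ΔIEC and wild type mice. Genes of fat, sugar and drug handling were lower in the TLR4ΔIEC pooled column, and genes of epithelial defence, lymphocytes, plasma cells and cell division were higher. The highest ratio among well covered genes belonged to Ubd (chromosome 17, 37193892 to 37196095), an interferon-inducible ubiquitin-like protein, at 18.5 units in wild type and 115 units in TLR4ΔIEC, 5.95-fold higher. The lowest belonged to Fabp1 (chromosome 6, 71199827 to 71205023), a fatty acid binding protein of enterocytes, at 192 units in wild type and 20.02 units in TLR4ΔIEC, 9.16-fold lower. After Ubd, the highest log2 ratios were those of the chemokine Ccl8 (2.49), Ckap4 (1.85), the immunoglobulin joining chain Igj (1.79), the secreted scavenger receptor Dmbt1 (1.79), granzyme A (Gzma, 1.75), Ly6a (1.75), the mucosal pentraxins Mptx1 (1.72) and Mptx2 (1.70), serum amyloid A1 (Saa1, 1.61), uridine phosphorylase (Upp1, 1.61) and the desaturase Scd2 (1.45). After Fabp1, the lowest were those of Cyp2d26 (-2.67), cytidine deaminase (Cda, -2.63), Cyp2c55 (-2.46), adenosine deaminase (Ada, -2.31), the deiodinase Dio1 (-2.23), the scaffold protein Pdzk1 (-2.13), Angptl4 (60.1 units in wild type and 14.2 in TLR4ΔIEC, 4.01-fold lower), Clca6 (-1.92), the interferon-inducible Ifi27l2b (-1.90) and Ifi27l2a (-1.88), and selenoprotein P (Sepp1, -1.85).

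Of 8888 genes with a mean of at least 5 units, 115 were at least 2-fold higher and 248 at least 2-fold lower in the TLR4ΔIEC pooled column, and 95.9% lay within 2-fold. The standard deviation of the log2 ratio across genes was 0.48, and Pearson's r between the columns across genes, which are not independent replicates, was 0.96. Among the genes that differed by 2-fold, 31.7% were higher, a share that was 45.2% (155 higher and 188 lower) when the columns were scaled to the total without the 50 highest genes. The numbers higher and lower were 65 and 146 with a pseudocount of 5, 206 and 380 with a filter at 1 unit, 222 and 395 with no filter, and 58 and 130 with a filter at 20 units. Unnamed gene models and small noncoding RNAs made up 605 of the genes, with 29 higher and 53 lower by 2-fold. Mptx1 and Mptx2, Ifi27l2a and Ifi27l2b, and the Cyp2c and Cyp2d genes have near-identical relatives, and Pdzk1 overlaps Cd160 and other genes on the opposite strand, so the values of these genes are uncertain.

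**Figure D1:**
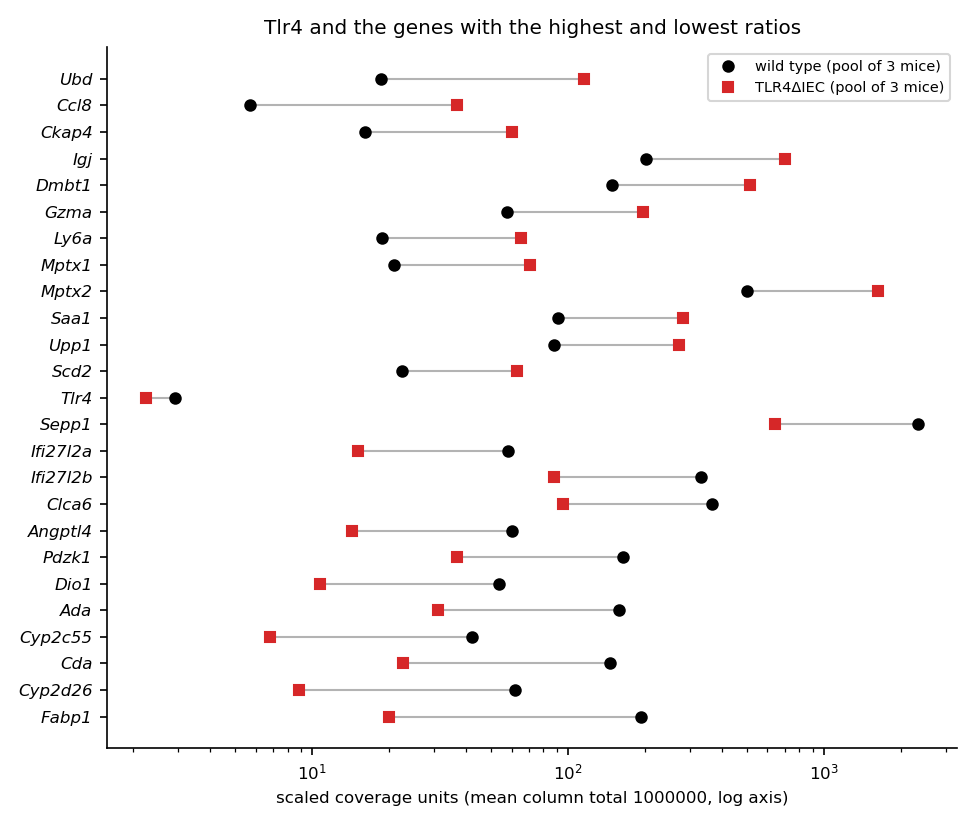
Scaled coverage units (log axis) of Tlr4 and of the 12 genes with the highest and the 12 with the lowest ratios, in the wild type (black circles) and TLR4ΔIEC (red squares) pooled columns, each a single value for 3 mice without an error. Ubd is at 18.5 in wild type and 115 in TLR4ΔIEC, Fabp1 goes from 192 to 20.02, and the points of Tlr4 lie at 2.90 and 2.24.

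Genes of fat absorption were lower in the TLR4ΔIEC pooled column: 15 of 17 measured members had a log2 ratio below 0, 5 were at least 2-fold lower and 0 at least 2-fold higher. Besides Fabp1, these included the apolipoproteins of chylomicrons and lipoproteins Apoa1 (10533 units in wild type and 3154 in TLR4ΔIEC, log2 ratio -1.74), Apoc3 (-1.47) and Apoa4 (-1.18). The list's median log2 ratio of -0.56 lay at the 0.17th percentile of matched random lists. Genes of PPAR signalling and fatty acid oxidation had a median of -0.26 (0.77th percentile), with 23 of 30 below 0, 5 at least 2-fold lower and 0 at least 2-fold higher. Members with low ratios included Angptl4 (4.01-fold lower), an inhibitor of lipoprotein lipase, the transcription factor Creb3l3 (-1.83) and the peroxisomal thiolase Acaa1b (-1.14), which overlaps Dlec1. Fatty acid synthesis genes, by contrast, had a median of 0.47 (99.95th percentile), with Scd2 (1.45), Acly (0.59) and Fads2 (0.47) higher and the regulator Mlxipl (-0.82) lower. Cholesterol synthesis and uptake genes had a median of -0.03, near the middle of the random lists (38.0th percentile), with 0 of 24 differing by 2-fold. The sterol transporters in that list were below 0, with Abcg8 at -0.91, Npc1l1 at -0.58 and Abcg5 at -0.54. The PPAR median was -0.16 with scaling to the total without the 50 highest genes, and that of fatty acid synthesis was 0.29 with a filter at 1 unit or none, both still outside the central 95%.

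Sugar and drug metabolism followed the fat absorption genes. Carbohydrate digestion and sugar handling genes had a median of -0.51 (0.12th percentile), with 10 of 13 below 0, 3 at least 2-fold lower and 1 at least 2-fold higher. Ketohexokinase (Khk), the first enzyme of fructose breakdown, was at -1.54, Pck1 at -0.55 and Pklr at -0.52. Xenobiotic metabolism genes had a median of -0.39 (0.08th percentile), with 18 of 22 below 0 and 6 at least 2-fold lower, among them Cyp2d26, Cyp2c55, Cyp4f14 (-1.08) and Cyp2c65 (40.9 units in wild type and 19.9 in TLR4ΔIEC). Peptide digestion and amino acid transport genes had a median of -0.26 (5.22nd percentile), with Slc6a20a at -1.20, Mep1a at -0.86 and Slc6a19 at -0.67. Bile acid handling genes, some of which mark the ileum, had a median of -0.23 (10.5th percentile). Of 10 measured members, 8 were below 0, 1 was at least 2-fold lower and 1 at least 2-fold higher. Among the well covered members, Fgf15 was at -0.63, Slc51a at -0.56, Nr1h4 at -0.19 and Slc51b at -0.17. Counting only genes of at least 20 units left the sugar list at -0.51 but at the 3.74th percentile, inside the central 95%, and its median was -0.34 with quantile normalization and -0.29 with no filter. With the trend on GC content and length removed, peptide digestion (-0.33) and bile acid handling (-0.36) lay below the central 95%.

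Markers of other tissue, of RNA handling and of enteroendocrine cells moved in the same direction as these metabolic genes. All 4 measured adipose tissue genes were at least 2-fold lower in the TLR4ΔIEC pooled column (median -1.50), namely Cfd (-1.70), Car3 (-1.55), Cidec (-1.45) and Adipoq (-1.26), named after their values were seen because none reached 20 units. Immediate early and heat shock genes, which respond to stress and handling of tissue, had a median of -0.73, below all of the random lists, with Junb at -1.51, Fos at -1.45, Jun at -1.06 and Btg2 at -0.91. Abundant noncoding RNAs had a median of -0.52 (0.34th percentile), with the RNase P RNA Rpph1 at -1.46 and the RNase MRP RNA Rmrp at -1.02, although Rnu12 was higher (0.84). Enteroendocrine genes had a median of -0.69 (0.01th percentile), with 7 of 10 measured members below 0 and 3 above. The hormones secretin (Sct, -1.75), neurotensin (Nts, -1.72) and peptide YY (Pyy, -1.36) were at least 2-fold lower, and Chgb was at -0.64. The hormone gene Gcg, chosen after its value was seen, was nearly equal in both columns (61.3 units in wild type and 61.4 in TLR4ΔIEC). With no filter on low values the enteroendocrine median was -0.16, inside the central 95%, and the adipose median was -0.60.

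**Figure D2:**
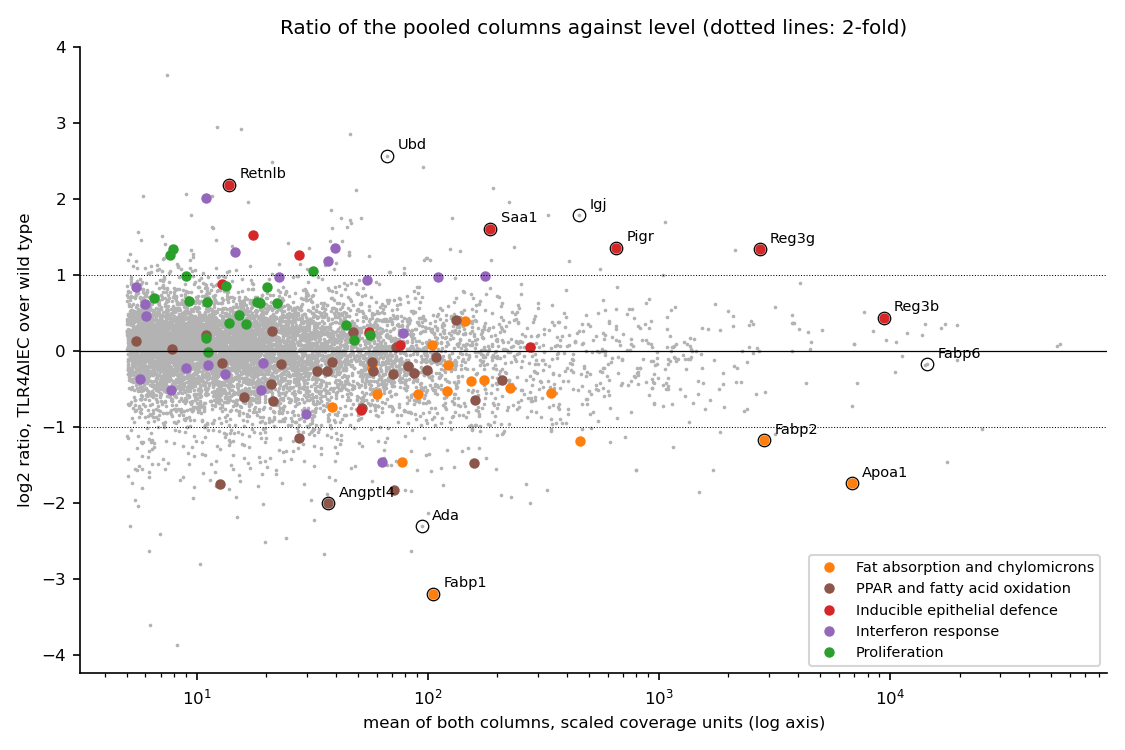
Log2 ratio of TLR4ΔIEC over wild type against the mean of both pooled columns in scaled coverage units (log axis) for 8888 genes (grey), with 5 gene lists in colour, dotted lines at 2-fold and circled genes named. Fat absorption genes such as Apoa1 (-1.74) lie below 0 at high levels, and defence genes such as Reg3g (1.34) lie above it.

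Inducible epithelial defence genes were higher in the TLR4ΔIEC pooled column: 11 of 12 measured members had a log2 ratio above 0, 6 were at least 2-fold higher and 0 at least 2-fold lower. Saa1 (1.61), the polymeric immunoglobulin receptor Pigr (1.36), which carries IgA across the epithelium, the antimicrobial lectin Reg3g (1545 units in wild type and 3918 in TLR4ΔIEC, 1.34) and the inducible nitric oxide synthase Nos2 (1.27) led the well covered members. The list's median of 1.08 lay above all 10000 random lists, and was 0.44 with a filter at 20 units (99.8th percentile) and 0.43 with no filter. Paneth cell products had 18 of 20 members above 0 and a median of 0.25 (99.9th percentile), about that of housekeeping genes (0.24, 12 of 15 above 0). Only Mptx1 and Mptx2 in that list were at least 2-fold higher, while Defa26 was at 0.55 and Defa25 at 0.48. Lysozyme (Lyz1, 0.15) and the most abundant defensin, Defa24 (0.07), chosen after their values were seen, differed little. Defensin genes are near-identical copies whose values are uncertain one by one.

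Interferon response genes had a median of 0.46, above all random lists (0.29 to 0.97 over the alternative settings). Of 21 measured members, 12 lay above 0 and 9 below, with 4 at least 2-fold higher and 1 at least 2-fold lower. The list was thus split, and its median does not stand for a rise of all members. Higher members were the GTPase Igtp (1.36, which overlaps Irgm2 on the same strand), the peptide transporter Tap1 (1.19, which overlaps Psmb9) and the immunoproteasome subunit Psmb8 (0.98). The transcription factor Irf7, which overlaps Phrf1 on the opposite strand, was lower (-1.46). MHC class II genes had a median of 0.30 (97.9th percentile), with H2-DMa at 0.68, Cd74 at 0.61, H2-Eb1 at 0.45 and H2-DMb2 at 0.30. The MHC class II median lay inside the central 95% with a filter at 1 or 20 units or with none. Other Toll-like and NOD receptors had a median of 0.43 over 5 measured genes, at the edge of the random lists, and lay inside the central 95% with quantile normalization (0.39), with a pseudocount of 5 (0.28) and among genes whose averages rested on the same length in both columns (0.16). Cytokines and chemokines had a median of 0.13 and a mean of -0.09, opposite in sign, with Ccl5 at 0.68 and Ccl25 at -0.82. A filter at 1 unit put that median at 0.30, above the central 95%.

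Lymphocyte, plasma cell and macrophage genes were higher in the TLR4ΔIEC pooled column. All 9 measured genes of T cells and intraepithelial lymphocytes had ratios above 0 (median 0.71, above all random lists), with Gzma at 1.75 and the T cell receptor component Cd3g at 0.85. Igj (202 units in wild type and 702 in TLR4ΔIEC) and Mzb1 (1.16), products of antibody-secreting cells, were higher in the B and plasma cell list, while Xbp1 was at 0.50 and the B cell receptor component Cd79a was at -0.06. That list's median was 0.50 (99.9th percentile), with 3 of 9 at least 2-fold higher and 1 at least 2-fold lower. Macrophage and dendritic cell genes had a median of 0.45 (99.9th percentile), with Lyz2 at 1.01, Csf1r at 0.95, C1qb at 0.72 and C1qc at 0.39. Globin genes of red blood cells were also higher, with all 6 measured members at least 2-fold higher (median 1.23). Hba-a1 and Hba-a2, whose values were nearly the same, were both at 1.23, and Hbb-bt and Hbb-b2, whose values were identical, were at 1.27. The 6 members are thus not 6 separate measurements. A filter at 1 unit or none brings in weakly covered B cell genes. The median of the B and plasma cell list then turned to -0.30. That median lay at the 0.575th percentile of random lists with a filter at 1 unit and at the 0.3rd with none. The list thus went from above nearly all random lists to below nearly all of them.

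Cell division genes were higher in the TLR4ΔIEC pooled column, with 19 of 20 measured proliferation genes above 0, 3 at least 2-fold higher and a median of 0.64 that lay above all random lists. The replication helicase subunit Mcm6 was at 1.05, cyclin A2 (Ccna2) at 0.85, cyclin B2 (Ccnb2) at 0.63 and Ube2c at 0.35. Crypt stem cell genes had a median of 0.47 (99.8th percentile), with Prom1 at 0.78, Olfm4 at 0.75, Cdca7 at 0.58 and Smoc2 at 0.54, and 0 of 8 reached 2-fold. Unfolded protein response genes had a median of 0.30 (99.8th percentile), with the chaperones Pdia4 (0.74), Hsp90b1 (0.66) and Dnajb9 (0.61) higher and the transcription factor Atf4 lower (-0.85). Housekeeping genes were at a median of 0.24 (98.5th percentile), with Tfrc at 0.80, Gusb at 0.66, Sdha at 0.39 and Rplp0 at -0.41. The crypt stem cell median was 0.21 with a filter at 1 unit or none and 0.32 among genes of the same length, and the housekeeping median was 0.16 with the trend on GC content and length removed, all inside the central 95%.

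**Figure D3:**
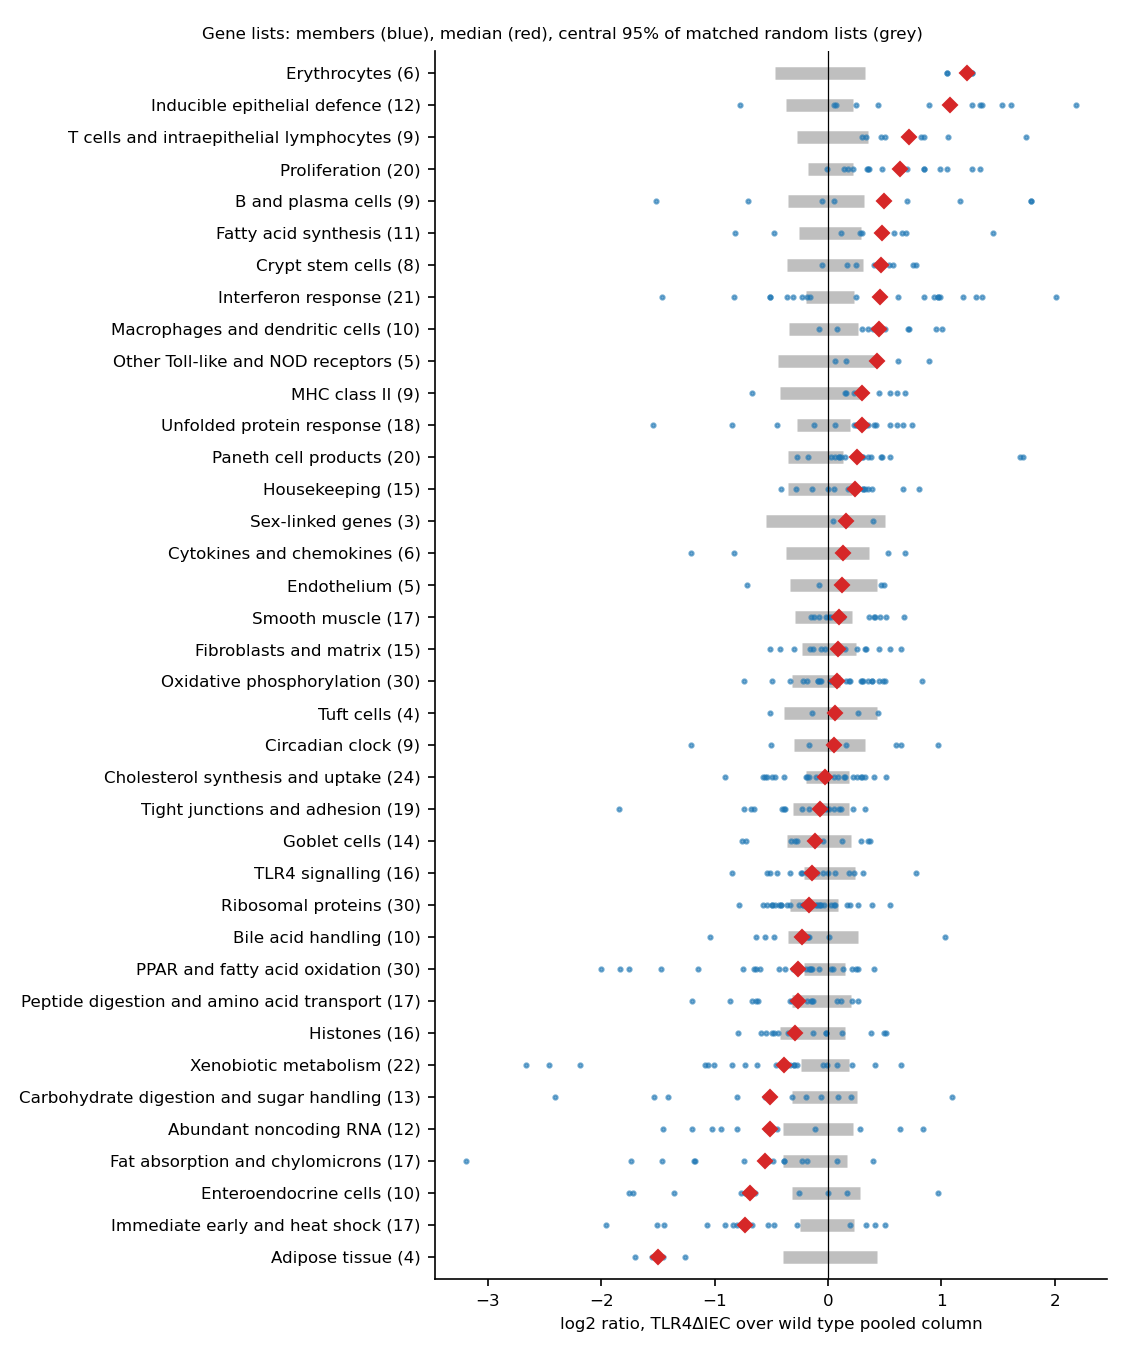
Log2 ratio of TLR4ΔIEC over wild type for the measured members (blue points) of 38 gene lists, with each list's median (red diamond), the number of members in brackets and the central 95% of 10000 random lists matched on expression (grey bar). Inducible epithelial defence (1.08) lies above its bar and fat absorption (-0.56) below it, while TLR4 signalling (-0.14) lies inside.

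The medians of other cell types and structures lay inside the central 95% of random lists. Goblet cell genes had a median of -0.12 (31.1th percentile), with Tff3 at -0.76, Zg16 at -0.72, Fcgbp at -0.29 and Spink4 at 0.35. Smooth muscle genes were at 0.10, with Mylk at 0.67 and Acta2 at 0.46, fibroblast and matrix genes at 0.09, with Dcn at 0.65 and Mgp at -0.42, endothelial genes at 0.13 and tuft cell genes at 0.06. Tight junction and adhesion genes were at -0.07, with 1 of 19 at least 2-fold lower, the claudin Cldn4 (-1.84), and with Cldn3 at -0.74. Both this median and that of the cholesterol genes turned slightly above 0 when the columns were scaled to the total without the 50 highest genes (0.02 and 0.08). The cholesterol median was also above 0 with scaling to the total (0.04) and quantile normalization (0.01). With the trend on GC content and length removed, smooth muscle (0.23, 98.96th percentile) and oxidative phosphorylation (0.18, 99.3rd percentile) lay above the central 95%, the latter also with quantile normalization (0.24). Oxidative phosphorylation genes were at 0.08 before that, ribosomal protein genes at -0.17, histone genes at -0.29 and circadian clock genes at 0.05. Sex-linked genes had a median of 0.16 over 3 measured genes. Neutrophil, mast cell, enteric neuron and pancreas lists had fewer than 3 measured genes and gave no value. Of the 38 lists with a value, 14 medians lay above and 8 below the central 95% of random lists, where chance among independent genes gives 1.90 in both directions together, and genes of a list are not independent.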

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

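Removing the trend with GC content and length, and keeping only genes with the same length behind both averages, were chosen after the data were seen, and the other 10 settings were planned. Of 297 values of the 25 named genes, 0 changed sign. A pseudocount cannot change the sign of a ratio, and filters and the choice of genes leave a gene's ratio as it is. Only the other scalings, the mean over entries and the removed trend could have changed a sign. Apart from Tlr4, the named genes were chosen for extreme ratios (1.45 or more, or -1.85 or less). Their unchanged signs were thus nearly certain beforehand and are a weak check. Of 22 lists outside the central 95% of random lists, 15 stayed outside on the same side in every setting run, 13 of them in 12 settings and 2 in 11, as adipose and T cell genes had too few members of 20 units. Of 261 values of these 22 lists, 233 stayed on their side and within 1.5 times the log2 median, 26 did not and 2 changed sign. Among the lists inside the central 95%, with 188 values, 6 values moved outside it, and 11 values of 6 lists changed sign. Genes at least 2-fold higher and lower numbered 65 and 146 with a pseudocount of 5, 206 and 380 with a filter at 1 unit, 222 and 395 with no filter, and 58 and 130 with a filter at 20 units. With a filter at 1 unit and with none, the B and plasma cell median was -0.30, below the central 95%, where it had been above it. In the same settings, medians were 0.21 for crypt stem cells and 0.26 for MHC class II, both inside the central 95%, and 0.29 for fatty acid synthesis. Those for enteroendocrine cells were -0.25 and -0.16, the latter inside the central 95%. No filter also gave -0.60 for adipose tissue, 0.43 for inducible defence and -0.29 for sugar handling. A filter at 20 units gave 0.44 for inducible defence, 0.97 for interferon response, 0.30 for MHC class II and -0.51 for sugar handling, the last 2 inside the central 95%. Quantile normalization gave -0.34 for sugar handling and 0.39 for other Toll-like and NOD receptors, a pseudocount of 5 gave 0.28 for these receptors (both of theirs inside the central 95%) and 0.29 for interferon response, and scaling without the 50 highest genes gave -0.16 for PPAR genes. Without the trend on GC content and length, interferon response was at 0.29 and housekeeping at 0.16. Among genes of the same length, interferon response was at 0.84, MHC class II at 0.45, crypt stem cells at 0.32 and other Toll-like and NOD receptors at 0.16, the last 2 inside the central 95%. Filters change which genes are counted. For the other moves the cause was not tested. No paired analysis was possible because the columns carry no mice and the groups share no replicate numbers. Leaving out single mice, array weights, robust variance estimates and an estimated correlation between genes were not run, as each needs values per mouse. Low coverage limits weakly covered genes, Tlr4 among them.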

Other observations

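The tests on the distal gut and on lymphoid follicles were chosen after the results they bear on had been seen, and the genes of this and the next paragraph were chosen after their values were seen, so they test no group. Of 5 genes of vitamin A handling picked in this way, Rbp2 and Rdh7 were more than 2-fold lower in the TLR4ΔIEC pooled column. The retinol binding protein Rbp2 was at 514 scaled units in wild type and 144 units in TLR4ΔIEC (log2 ratio -1.82), and the retinol dehydrogenase Rdh7 was at -1.57, while Aldh1a1 was at -0.74, Retsat at -0.64 and the transcription factor Isx at -0.32. Among enzymes that act on nucleosides, Ada (-2.31), Cda (-2.63) and Tymp (-1.23) were lower, Upp1 was higher (1.61), and Pnp (-0.03) and Adk (0.15) were nearly equal in both columns.

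Single interferon-inducible genes lay on both sides of 0, and no list was split by type of interferon. Higher in the TLR4ΔIEC pooled column were Ubd at 2.57 and GTPases, with Tgtp1 at 2.07, Iigp1 at 2.01, Tgtp2 at 1.64, Irgm2 at 1.38, Igtp at 1.36 and Gbp2 at 1.31. Lower were Ifi27l2b at -1.90, Ifi27l2a at -1.88, Rtp4 at -1.48, Irf7 at -1.46, Isg15 at -0.83, Oas1a at -0.51 and Ifit1 at -0.51. Bst2 was at 0.64, Ido1 at 0.11 and Socs1 at -0.45. Tgtp1 and Tgtp2 are near-identical copies.

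The fat absorption list had a median of -0.56 in the comparison of the columns. A trend of the ratio with GC content and transcript length does not account for it, as the median was -0.59 with the trend removed. A more distal piece of ileum in the TLR4ΔIEC pool cannot be told apart from other causes. It would raise distal genes, but 11 of them had a median of -0.56 (0.17th percentile, 9 below 0). Nts (-1.72), Pyy (-1.36) and Amn (-0.94) were low, and Fabp6 (-0.17), Slc10a2 (0.01) and Gcg were near 0. Proximal genes, which it would lower, had a median of -1.82 over the 3 measured outside the fat absorption list and the 12 lowest ratios. That median lay below all random lists, with Cyp3a11 (-2.19) and Rbp2 (-1.82) lower and Slc40a1 (0.51) higher. Cyp3a11 belongs to the xenobiotic list and Rbp2 was named above after its value was seen, so these 3 genes are no independent check. Fewer cells of the villus tip may contribute, since the median of 5 tip genes was -1.26 (0.015th percentile), with Nt5e (-2.02), Slc28a2 (-1.36) and Clec2h (-1.26) lower, although Bsg (0.08) and Krt20 (0.01) were not. An effect of the Tlr4 deletion also stays open, and it cannot be told apart from the sequencing pools or from differences between single mice.

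Inducible defence genes had a median of 1.08, and removing the trend with GC content and length left it at 0.97, which argues against that trend as the whole cause. More cells of the villus base, where several defence genes are expressed, remain possible. Of the measured base genes, 4 of 4 were above 0, with a median of 0.39 (98.4th percentile). Housekeeping genes lay at a like percentile (98.5th, 12 of 15 above 0), so this result does not single out the villus base. The defence median was 0.44 among genes of at least 20 units, over members from -0.77 (Reg3a) to 1.61 (Saa1), while the base genes reached 0.68 (Plac8) and housekeeping genes had a median of 0.24. An effect of the deletion stays open and untested, with the sequencing pools confounded with it.

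The plasma cell genes were higher with a sum of 355 units in wild type and 953 units in TLR4ΔIEC (log2 ratio 1.42, bootstrap interval over genes 0.56 to 1.79). More lymphoid follicle in the TLR4ΔIEC pool would raise follicle B cell genes alike, and their sum over 10 genes was at -0.36 (-1.56 to -0.09). The follicle genes were weakly covered, with sums of 82.4 and 64.4 units. Cd79a (-0.06) and Cd79b (0.05) had the highest values among them and were near equal in both columns, while the others were lower. Igj alone gave 702 of the 953 plasma cell units in TLR4ΔIEC. The intervals resample a few genes of 1 pooled value per genotype. They give no spread between mice or pools, so more lymphoid follicle is not excluded. More plasma cells outside follicles, more product per cell and a single mouse with high values were not tested and stay open.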
